A study of Homo sapiens with 22 samples.

How the data were processed

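The samples were libraries of MCF7 cells, a luminal, oestrogen receptor positive human breast cancer cell line. Actinomycin D (ActD), which blocks transcription, was given for 0, 2, 4 or 6 h, and external RNA was added to every sample after RNA isolation, per the labels. The control arm held 3 libraries at each of the 4 times, 12 in all. The arm treated for 24 h with 6 µM CPT (camptothecin, a poison of DNA topoisomerase I) held 2 at each time, 8 in all. These 20 libraries were 3-prime tag libraries (MARS-seq). A further 2 libraries held RNA labelled with 4-thiouridine (4sU), which marks newly made RNA, pulled down and depleted of ribosomal RNA without selection for poly(A). All 22 samples were assigned to a group from their titles, because the treatment label named CPT on every sample, the control libraries included.

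The values came from a single table that the authors deposited, with 33606 rows, 2 half-life columns and 1 column of 4sU signal. Each gene had the authors' single half-life for the control time course and another for the CPT time course, with no error and no value per library. The unit was taken to be hours from the time course and the column names, and no half-life exceeded 24. The authors' 4sU column was read as a signal, an abundance on a linear scale per the file headers and the values; whether it was TPM or FPKM was not given in the sources used here. All 4sU values were whole multiples of 0.005, within a tolerance of 1e-06 steps, as a mean of 2 values printed to the second decimal would be. The submitters' processing notes named Bowtie2, STAR and RSEM and the builds hg19 and mm9, without version or role. How half-lives were fitted, how replicates were joined, how the spike was used and which genes were left out was not given in the sources used here. The depth of the libraries is unknown.

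The gene was the unit of analysis. The 29 rows for copies on the pseudoautosomal part of the Y chromosome were left out, and 27 symbols that a spreadsheet had turned into dates were replaced by the symbol of the gene identifier. Of 34 symbols with several identifiers, 11 had a control half-life; in all 11 the identifiers shared a single half-life and had different 4sU signals, so half-lives had been joined by symbol. Such symbols were reduced to the identifier with the highest 4sU signal, which left 33542 genes. Identifiers of 32465 of these were found in the gene name table. Gene span, transcript length and 3-prime UTR were taken by gene identifier from the GENCODE annotation of GRCh38, which is not the build named by the submitters, and no coordinates are given for that reason.

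With a single derived value per gene, no test per gene was possible, and the tests planned for counts were replaced by the descriptions planned for this case. Shares have exact Clopper-Pearson 95% intervals over genes, which do not cover error between cultures. Relations across genes were given as Spearman's rho and Pearson's r of log2 values, with 1 added to the 4sU signal, and a two-sided permutation test with 100000 permutations; genes are not independent replicates. Benjamini-Hochberg adjustment ran over 3 relations, of which the relation with the CPT half-life was added after the data were seen. The 22 gene lists were fixed before the data were examined, and the 20 with at least 5 members measured were tested. The median log2 half-life of a list was set against 10000 random lists of the same size, matched on 10 equal groups of the 4sU signal; this is a permutation test of list membership within those groups, two-sided, with Benjamini-Hochberg adjustment over the lists for each measure and a threshold of 0.05. On simulated data made from the 9423 control half-lives, the list test called 2.5% of lists of 15 genes and 5% of lists of 60 genes with no shift. For the control half-life it called 42.5% of lists of 15 and 95% of lists of 60 after a log2 shift of -1, and 10% and 37.5% after a shift of -0.5. All of these simulated calls used the p of a list without adjustment over lists. The adjusted p used for the real lists can only call fewer.

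Named genes followed a rule fixed before the data were examined. It took the 10 highest and the 10 lowest protein-coding genes of each measure with a 4sU signal above the median of genes with a half-life (6.60), up to 4 members of each list, namely the 2 highest and the 2 lowest, and 12 fixed genes. The highest control and CPT half-lives are tied at 24 h and were not ranked; ties within a list were broken by the 4sU signal, a choice made after the data were seen. Alternatives were genes above the median 4sU signal, half-lives under 0.5 h left out, relations without ribosomal protein and respiratory chain genes, and lists without matching. Alternatives added after the data were seen were values at 24 h left out, protein-coding genes only, pseudocounts of 0.1 and 5, genes listed at 0 left out, relations without mitochondrial transcripts, and lists scored by their mean or by their share at 24 h. Random lists matched on the control half-life were also added then. The comparison of CPT with control at 0 h was left out because the table holds half-lives and 4sU signal and no expression level of either arm. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.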

Results

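The data describe how fast messenger RNA was lost in MCF7 breast cancer cells, with and without the topoisomerase I poison CPT. They also give the abundance of newly made, labelled RNA of each gene. Half-lives came from an ActD time course of 0, 2, 4 and 6 h, with 12 control libraries and 8 libraries of cells kept in CPT for 24 h. The signal of new RNA came from 2 libraries of 4sU-labelled RNA. The table held a control half-life for 9423 genes, a CPT half-life for 9262 and a 4sU signal for 33522. Every value is the authors' single value for a gene, without replicate values or an error, and the depth of the libraries is unknown.

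The control time course asks how long each transcript lasts in untreated cells. The shortest listed half-life among well transcribed genes was that of MYC (ENSG00000136997.16_2), a growth-promoting transcription factor, at 0.306 h. EGR1, an early growth response factor, followed at 0.309 h, then the kinase gene PLK2 at 0.353 h, NFKBIA, which encodes an inhibitor of NF-kappa-B, at 0.359 h, and DDIT4, a stress-induced inhibitor of mTOR signalling, at 0.362 h. JUNB (0.383 h), ZNF296 (0.388 h), GADD45B (0.401 h), IRF1 (0.427 h) and ZFP36 (0.430 h) completed the 10 shortest. These values lay below the first ActD time after 0 h, 2 h, and have no error estimate, so their order is uncertain. At the other end, GAPDH, ACTB, PABPC1, which encodes the main cytoplasmic poly(A)-binding protein, and CNOT1, the scaffold of the CCR4-NOT deadenylase, were all listed at the limit of 24 h. TOP1, the enzyme that CPT poisons, was listed at 14.1 h.

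Across the 9423 genes the median control half-life was 7.31 h, with quartiles of 3.09 and 24 h. A total of 388 genes were listed under 1 h and 1381 under 2 h. Another 2563 genes, 27.2% (95% interval 26.3 to 28.1), stood at exactly 24 h, so their order is unknown. The 6860 genes below that limit had a median of 4.62 h.

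Of 20 gene lists tested in control cells, 3 had shorter and 2 longer half-lives than random lists matched on 4sU signal. Immediate early genes, which switch on within minutes of a stimulus, had a median of 0.533 h (n = 20 measured members), against 10.6 h for the random lists (adjusted p = 0.00200, permutation test of list membership). None of the 20 stood at 24 h, and members ran from MYC and EGR1 to SOCS2 at 1.97 h and JUND at 2.59 h. C2H2 zinc finger genes, a large family of transcription factors, were taken here as all genes whose symbol begins with ZNF. Neither their gene type nor their protein domains were checked, and family members with other names are not in the list. They had a median of 1.69 h (n = 237 genes) against 6.63 h (adjusted p = 0.00200, permutation test). Members ran from ZNF34 at 0.361 h to 16 genes at 24 h, among them ZNF385A and ZNF358. Targets of p53 had a median of 2.31 h (n = 20 genes) against 8.11 h (adjusted p = 0.00400). Scored by the share of members at 24 h, the p53 list just missed the threshold (n = 20 genes, adjusted p = 0.0525). Among them SESN2 was listed at 0.461 h and the phosphatase gene PPM1D at 0.514 h, whereas BAX, a promoter of apoptosis, was listed at 16.6 h and TP53I3 at 24 h. CDKN1A, the cell cycle inhibitor p21, was listed at 5.48 h and MDM2, which encodes the ubiquitin ligase of p53, at 2.53 h.

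The 2 lists with longer half-lives were ribosomal protein genes and nuclear genes for the respiratory chain. Of 79 measured ribosomal protein genes, 76 stood at 24 h, including RPL41 and RPL13A, with RPL36A at 3.08 h and RPL39 at 7.36 h as the shortest (list median 24 h against 11.2 h, n = 79 genes, adjusted p = 0.0368). Above the median 4sU signal the ribosomal list no longer passed the test (n = 66 genes, adjusted p = 0.222, permutation test). Its log2 difference from random lists was 0.79 there, against 1.10 over all genes. Over all genes the ribosomal list passed by the share at 24 h (96.2% against 35.4%, n = 79 genes, adjusted p = 0.00100, permutation test). The mean log2 half-life passed as well (4.52 against 3.14, n = 79 genes, adjusted p = 0.000571, permutation test). Of 71 nuclear genes for the respiratory chain and ATP synthase, 66 stood at 24 h, with UQCRFS1 at 7.20 h and SDHA at 7.80 h as the shortest (24 h against 8.57 h, n = 71 genes, adjusted p = 0.00600). Glycolytic genes did not pass the test on their median (n = 16 genes, adjusted p = 0.239), although 13 of 16 stood at 24 h, GAPDH and ALDOA among them; HK2 was listed at 5.07 h and HK1 at 5.71 h. Scored by the share at 24 h they passed (81.3% against 31.3%, n = 16 genes, adjusted p = 0.00100), and by the mean as well (n = 16 genes, adjusted p = 0.000571). The median of the histone genes was also 24 h (n = 10 genes, adjusted p = 0.309), with HIST1H3D at 1.58 h and HIST1H2AC at 22.6 h below it. Histone genes also passed by the share at 24 h (80% against 30%, n = 10 genes, adjusted p = 0.0177, permutation test) and by the mean (n = 10 genes, adjusted p = 0.0220). Half-lives came from 3-prime tag libraries, and which forms of the histone transcripts these captured was not tested. The values may not hold for all histone transcripts. Mitochondrial transcripts had the same median (n = 13 genes, adjusted p = 0.607), with MT-ND6 at 1.56 h and MT-ND3 at 3.18 h as the shortest.

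**Figure D1:**
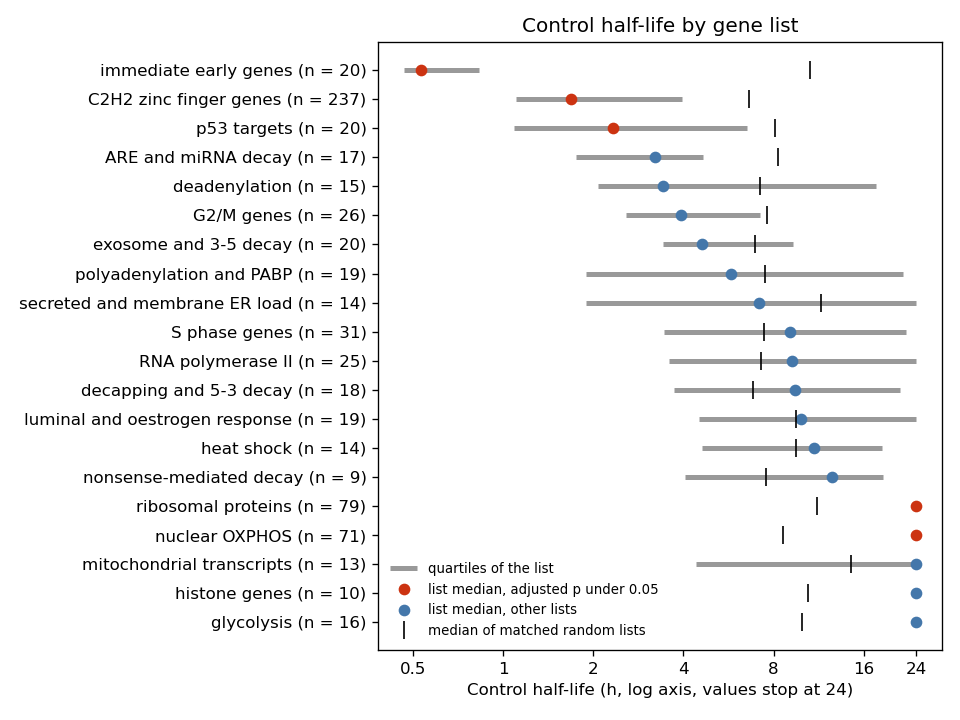
Control half-life in hours (log axis, values stop at 24) for 20 gene lists. Dots are list medians, red where the adjusted p of the random list test was under 0.05, grey bars are quartiles and black ticks are medians of matched random lists; immediate early genes sit at 0.533 h and ribosomal protein genes at 24 h.

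The RNA decay machinery, which the title of the study names, was mixed in control cells, and none of its lists passed the test on the median. Genes of AU-rich element and microRNA decay came closest, with a median of 3.22 h (n = 17 genes) against 8.28 h (adjusted p = 0.0513). They passed under both scores added after the data were seen, the mean log2 half-life (1.40 against 2.92, n = 17 genes, adjusted p = 0.000571) and the share at 24 h (0% against 29.4%, n = 17 genes, adjusted p = 0.0113). None of them stood at 24 h; ZFP36 (0.430 h) and ZFP36L2 (0.439 h), which encode proteins that bind AU-rich elements, were shortest, and KHSRP (6.96 h) and HNRNPD (8.49 h) longest. Deadenylation genes had a median of 3.41 h (n = 15 genes, adjusted p = 0.152), with the adaptor genes TOB1 (0.726 h) and BTG1 (0.736 h) at one end and the enzyme subunits CNOT1 and CNOT7 at 24 h at the other. Decapping genes ranged from DCP1B (1.16 h) and DCP1A (1.47 h) to LSM4 and LSM7 at 24 h, with the decapping enzyme gene DCP2 at 5.13 h (n = 18 genes, adjusted p = 0.607). Exosome genes had a median of 4.61 h (n = 20 genes, adjusted p = 0.407), from RBM7 (1.33 h) and ZCCHC8 (1.39 h) to HBS1L and WDR61 at 24 h, and EXOSC10, a nuclear exoribonuclease, stood at 4.22 h. Nonsense-mediated decay genes ran from SMG6 at 2.37 h and SMG1 at 3.28 h to UPF2 and UPF3B at 24 h (9 genes, adjusted p = 0.607, permutation test). XRN1, the cytoplasmic 5-prime exonuclease, had no half-life in either column.

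Polyadenylation factors (median 5.77 h, n = 19 genes, adjusted p = 0.607) included CSTF1 at 1.01 h and CLP1 at 1.10 h. RNA polymerase II genes (9.23 h, n = 25 genes, adjusted p = 0.607) ran from the elongation factor gene ELL (0.808 h) and HEXIM1 (1.05 h) to POLR2L and SUPT4H1 at 24 h. Luminal markers of MCF7 cells had a median of 9.91 h (n = 19 genes, adjusted p = 0.949); the lineage factors FOXA1 (0.625 h) and GATA3 (1.19 h) were shortest, and the oestrogen-responsive TFF1 and CTSD stood at 24 h. Mitotic genes had a median of 3.93 h and did not pass (n = 26 genes, adjusted p = 0.0948), with PLK1 at 1.70 h, BUB1B at 1.91 h, and PTTG1 and CDK1 at 24 h. S phase genes (n = 31 genes, adjusted p = 0.607) ran from CCNE1 at 0.921 h and CDT1 at 1.13 h to TYMS and MCM4 at 24 h. Heat shock genes (n = 14 genes, adjusted p = 0.864) ran from DNAJB1 at 1.15 h and BAG3 at 1.85 h to HSP90AA1 and HSPD1 at 24 h. Genes of the endoplasmic reticulum (n = 14 genes, adjusted p = 0.603) ran from DDIT3 at 0.557 h and DNAJB9 at 0.708 h to PDIA3 and CANX at 24 h.

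After 24 h of CPT almost every transcript was listed as stable. Of 9262 genes with a CPT half-life, 8368 stood at 24 h, which is 90.3% (95% interval 89.7 to 90.9). All of the fixed genes with a CPT half-life, namely MYC, MDM2, CDKN1A, TOP1, DCP2, EXOSC10, CNOT1, CNOT7, PABPC1, GAPDH and ACTB, were listed at 24 h. The 894 genes below the limit had a median of 9.51 h, and only 23 were listed under 2 h. Shortest among well transcribed genes were ABCD4 (1.28 h), which encodes a transporter, the methyltransferase gene SETDB2, then PIGN (1.90 h), the chromatin remodeller gene CHD7 (2.15 h) and the mitochondrial transcript MT-ND3 (2.19 h), followed by NOL9, WDPCP, MACF1, KDM3B and BRD1 between 2.36 and 2.76 h.

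Every one of the 20 lists tested had a CPT median of 24 h, so the test on medians could separate none of them. Scored instead by the share of members at 24 h, a choice made after the data were seen, 2 lists passed. Of the mitochondrial transcripts, 6 were below the limit (n = 13 genes, adjusted p = 0.00400, permutation test), including MT-ND6 at 1.48 h and MT-ATP6 at 5.77 h. The test takes these 13 as independent genes, which was not checked. Of the C2H2 zinc finger genes, 51 were below it (n = 215 genes, adjusted p = 0.00400), including ZNF224 at 0.559 h and ZNF253 at 2.06 h. The share of zinc finger genes at 24 h was 76.3%, against 89.3% in the random lists. Against lists matched on the control half-life the zinc finger genes no longer passed (n = 178 genes, adjusted p = 0.0560).

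**Figure D2:**
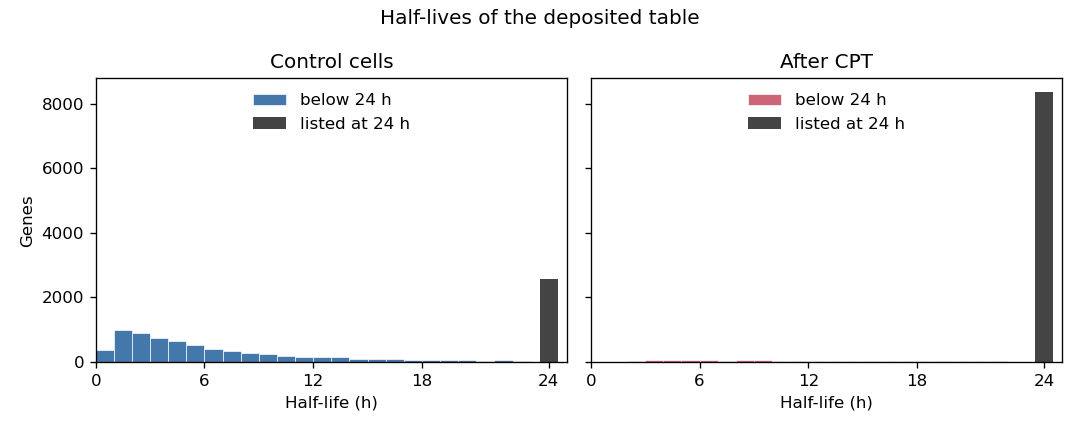
Number of genes by half-life in hours for control cells (left) and cells kept in CPT for 24 h (right), in bins of 1 h. The dark bar counts genes listed at exactly 24 h, 2563 of 9423 in control cells and 8368 of 9262 after CPT.

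The difference between the arms asks whether long CPT treatment alters decay. Of 8043 genes with both half-lives, 5534 were listed longer after CPT (68.8%), 147 shorter (1.83%) and 2362 stood at 24 h in both columns. Of the 5595 genes below 24 h in control cells, 98.9% were listed longer. In most of these, 5096 genes, the CPT value stood at the limit. The median log2 change of the listed values over all genes was 1.38, or 2.59-fold, with tied genes at 0; it is neither an estimate of the true change nor a bound on it, because CPT values stop at 24 h and the control values are given without an error estimate. Among the 499 genes below 24 h in both columns, which are selected by their CPT value, 438 were listed longer and 61 shorter, and their medians were 2.57 h in control cells and 9.82 h after CPT, a median log2 change of 1.87 (quartiles 0.66 and 2.86).

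The largest listed increases were those of genes with short control half-lives, because CPT values stop at 24 h. Among protein-coding genes above the median 4sU signal, the ratio of the listed values was highest for MYC, at 78.4-fold. PLK2 (67.9-fold), NFKBIA (66.9-fold), DDIT4 (66.2-fold) and JUNB (62.6-fold) followed, with ZNF296, GADD45B, ZFP36, ZFP36L2 and PHF13 between 54.3-fold and 61.9-fold. Control half-lives of these genes lay below the first ActD time after 0 h, 2 h, and are given without an error estimate, so the ratios are no bounds. EGR1 stayed below the limit after CPT, at 11.1 h, 35.9-fold longer than in control cells. Smaller ratios, with the CPT value also at 24 h, were those of MDM2 (9.50-fold), EXOSC10 (5.68-fold), DCP2 (4.68-fold), CDKN1A (4.38-fold) and TOP1, the target of CPT (1.70-fold). The largest listed decreases were also ranked among protein-coding genes above the median 4sU signal. They were those of PIGN, listed at 0.127 times its control value, EME2 (24 to 4.24 h), VEZT (24 to 4.76 h), DCTN6 (24 to 4.96 h) and APOD (24 to 5.25 h). MT-ATP6, RPS23, ABCD4, RPL21 and ATP5H completed the 10 largest decreases of this ranking.

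Immediate early genes (20 of n = 20 longer, median log2 change 5.43 against 0.93 for random lists, adjusted p = 0.00133), p53 targets (18 of 20 longer, 3.38 against 1.34, adjusted p = 0.00133) and C2H2 zinc finger genes (162 of 178 longer, 3.16 against 1.49, adjusted p = 0.00133) passed the permutation test on the change, which largely follows the control half-life because CPT values stop at 24 h. The respiratory chain list passed in the other direction, with a median of 0 against 1.22 (n = 71 genes, adjusted p = 0.0130); 60 of these stood at 24 h in both columns. Among genes above the median 4sU signal, the p53 list no longer passed, with a difference from random lists of 0.89 against 2.04 over all genes (n = 15 genes, adjusted p = 0.356). The respiratory chain list did not pass there either, although its difference stayed close, at -1.11 against -1.22 (n = 54 genes, adjusted p = 0.0747). Of the p53 targets, ZMAT3, named after its value was seen, was the exception listed shorter, from 4.31 to 3.73 h. Over all genes with both half-lives 1.83% were listed shorter, and 98.9% of those below 24 h in control cells were listed longer. Decay factor lists held no member listed shorter, which is therefore not particular to them. Listed longer were 14 of 14 genes of AU-rich and microRNA decay, 10 of 12 deadenylation, 13 of 17 decapping and 15 of 17 exosome genes. The rest of these decay factor genes stood at 24 h in both columns. On the median change, none of the decay factor lists passed (adjusted p = 0.0648 for AU-rich and microRNA decay and 0.0760 for deadenylation, permutation test). Scored by the mean log2 change, both of the lists just named passed, AU-rich and microRNA decay at 3.08 against 1.41 (n = 14 genes, adjusted p = 0.00100) and deadenylation at 2.59 against 1.55 (n = 12 genes, adjusted p = 0.0372). Lists that passed by this mean in the other direction included ribosomal protein genes (-0.08 against 1.28), mitochondrial transcripts (-0.11 against 1.07) and glycolytic genes (0.17 against 1.30). Their adjusted p was 0.000571 each (permutation test). Histone genes passed in that direction too (0.35 against 1.37, n = 10 genes, adjusted p = 0.0231, permutation test).

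Some genes had a half-life in one arm only, 1380 in control cells and 1219 after CPT. Of the immediate early genes, 11 had a half-life after CPT only, FOSB and ATF3 among them, named after their values were seen, and 0 in control cells only (adjusted p = 0.000708, Fisher's exact test). Of the mitotic genes, 8 had a half-life in control cells only, BUB1B among them, and 0 after CPT only (adjusted p = 0.0129, Fisher's exact test). C2H2 zinc finger genes did not pass, with 59 against 37 (adjusted p = 0.0966, Fisher's exact test). These 3 lists, with at least 5 such members each, were chosen for this test after the data were seen. CPT against control at 0 h could not be compared directly, because no expression level per arm was in the table.

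The 4sU libraries report the abundance of pulled-down labelled RNA of each gene. The 13 protein-coding mitochondrial genes took 44.0% of the summed signal, led by MT-ND4L at 40424, MT-ATP6 at 32192 and MT-ND4 at 29382. Among nuclear genes of the fixed set, ACTB had a signal of 2460, PABPC1 of 1655, GAPDH of 1217 and CDKN1A of 305, whereas MYC had 67.4 and XRN1 28.7. The markers named next were chosen after their values were seen. Luminal markers were present, with CTSD at 454, TFF1 at 239, KRT8 at 234 and GATA3 at 128. Mesenchymal markers were high as well: VIM, the intermediate filament vimentin, at 2734, the collagen genes COL1A1 at 2015 and COL1A2 at 279, and the matrix gene SPARC at 921, none of which had a half-life. FN1 (486) and TAGLN (409) had half-lives of 24 h in both columns. Other mesenchymal members were lower, from COL3A1 at 44.7 to ZEB2 at 5.36, and the basal keratin genes KRT5, KRT14 and KRT17 and TP63 were listed at 0. Of the 15 basal and mesenchymal markers, 10 lay above the median signal of genes with a half-life (6.60). Of 13 blood cell markers 8 were listed at 0, and LYZ (52.3) and CD68 (122) were the highest. With fewer than 5 measured half-lives, neither the mesenchymal nor the blood list was tested. Of 33522 genes, 55.1% were listed at 0.

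The 4sU signal and the control half-life were weakly related across genes. The signal is an abundance of pulled-down RNA and not a rate, and carry-over of unlabelled RNA was not tested. Only genes with a control half-life enter. Genes with a higher 4sU signal had longer control half-lives (Spearman's rho = 0.121, Pearson's r = 0.130, adjusted p = 1e-05 for both, permutation test, 9423 genes), where 1e-05 is the smallest p the permutations can give. Above the median 4sU signal both coefficients were 0.194 (4998 genes). The relation was not even over the range. The median control half-life was 8.02 h in the lowest decile of the signal, 5.54 h in the third decile and 16.2 h in the highest decile, where 43.7% of genes stood at 24 h. ACTB, GAPDH and PABPC1, all of high signal, stood at 24 h, whereas MYC combined a signal of 67.4 with a half-life of 0.306 h. The signal on which this rests held the mesenchymal markers VIM, COL1A1 and SPARC beside the luminal ones.

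**Figure D3:**
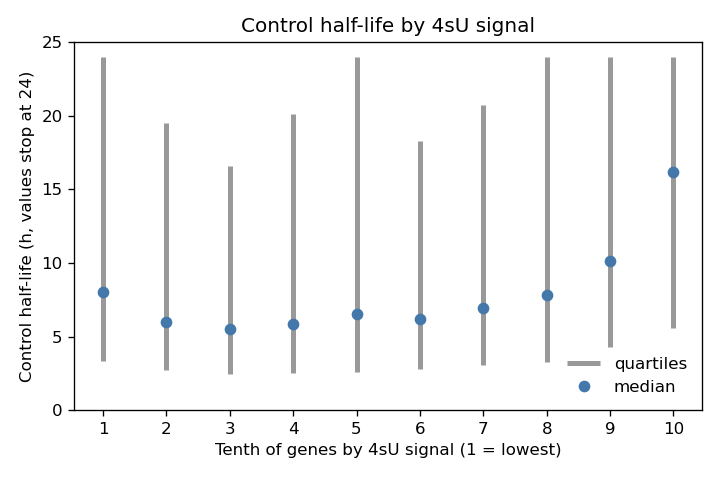
Control half-life in hours (values stop at 24) in 10 equal groups of the 9423 genes ordered by 4sU signal. Dots are medians and grey bars quartiles; the median was 8.02 h in the lowest group and 16.2 h in the highest.

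The listed change after CPT had the opposite sign, also weakly (rho = -0.0717, r = -0.0841, adjusted p = 1e-05 for both, permutation test, 8043 genes). It was rho = -0.165 and r = -0.174 above the median 4sU signal (4588 genes), rho = -0.109 without genes listed at 0 and r = -0.0541 with a pseudocount of 0.1. With 92.7% of these genes at 24 h after CPT, the listed change mostly restates the control half-life, and its sign follows from the relation above. ACTB and GAPDH stood at 24 h in both columns, whereas CDKN1A, with a signal of 305, was listed 4.38-fold longer. The CPT half-life itself was longer at a higher signal (rho = 0.113, r = 0.102, adjusted p = 1e-05 for both, permutation test, 9262 genes). Above the median 4sU signal rho fell to 0.0570 (p = 3e-05) and r to 0.0205, which did not pass (p = 0.150, permutation test, 4910 genes).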

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

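No paired analysis was possible because the table holds a single value per gene and arm, with no replicate columns. Not run for the same reason were other normalizations and spike scaling, other count tools, pseudocounts on values per library, leaving out replicates, the fit on 0 h libraries, the fit without 6 h, each 4sU replicate alone, and fry. Values at 24 h left out, genes below 24 h in both columns, protein-coding genes only, pseudocounts, other list scores and all settings of the CPT half-life relation were chosen after the data were seen, as was leaving out half-lives under 0.5 h from the summaries of each arm.

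Of 94 alternative values of the main results, 75 kept their direction and their side of the threshold or stayed within the interval or the 1.5-fold range of the main value. Some of the 75 could not change, since Spearman's rho is the same under any pseudocount. The CPT median, at the limit of 24 h, could hardly change, so the count overstates how stable the results are. Above the median 4sU signal, the control median was 8.47 h with 29.2% at 24 h, the CPT share at 24 h was 93.1%, genes listed shorter were 1.39%, the median log2 change was 1.30, 2 lists passed on the change, and Pearson's r of the 4sU signal with the CPT half-life was 0.0205 (p = 0.150, permutation test). With values at 24 h left out, the medians were 4.62 h in control cells and 9.51 h after CPT. Genes below 24 h in both columns were listed longer in 87.8% and shorter in 12.2%, with a median log2 change of 1.87, and the relation of the 4sU signal with the change had rho = 0.0912 and r = 0.0412; genes are selected here by the CPT value that enters the change, so this sign decides nothing. With protein-coding genes only, the CPT share at 24 h was 91.1%. Scored by the mean, 8 lists passed on the control half-life, 2 on the CPT half-life and 10 on the change; scored by the share at 24 h, 2 passed on the CPT half-life. The cause of the other shifts was not tested. Single lists gave 280 further values, of which 259 kept their call, 17 gained and 4 lost it. The 259 include the list medians of the CPT half-life, which tied with the random lists at 24 h and could hardly change. Depth is unknown, so its limits could not be set.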

Other observations

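Tests on the limit of 24 h, on mesenchymal markers, on matched control half-lives and the check on 3-prime UTR length were chosen after the results were seen; the predictions for gene length, genes in a single arm and AU-rich pentamers were written before.

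Genes listed in control cells only were longer than genes listed after CPT only. Genes with a half-life in control cells only spanned a median of 66.6 kb, genes with one after CPT only 14.0 kb and genes with both 25.7 kb, on GRCh38. The ratio of 4.77 between the first and the second had a p of 1e-05, the smallest the permutations can give, and among protein-coding genes it was 4.03 (71.8 against 17.8 kb, p = 1e-05). This fits the hypothesis that long genes fell below detection under a topoisomerase I poison, which may stall elongation. Low abundance is not excluded either, since the median 4sU signal plus 1 of genes in a single arm was 0.319 times that of genes in both (p = 1e-05, permutation test). With 1 p53 target among these genes, the odds ratio of 3.40 (p = 0.469, Fisher's exact test) decided nothing about their entry into the CPT arm.

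Ribosomal protein genes and mitochondrial transcripts were below 24 h after CPT more often than genes with matched control half-lives. By a permutation test of list membership, this held for 11.5% of 78 ribosomal protein genes, RPS23 and RPL21 among them, against 3.85% in random lists (adjusted p = 0.0460), and for 46.2% of 13 mitochondrial transcripts against 7.69% (adjusted p = 0.00400). The test takes the mitochondrial transcripts as 13 independent genes, which was not checked. If they vary together, this p is too small. Matched on the 4sU signal instead, the ribosomal list did not pass (88.6% at 24 h against 93.7%, n = 79 genes, adjusted p = 0.631, permutation test). That test also drew on all genes with a CPT half-life rather than on genes with both half-lives. The ribosomal call therefore depends on the matching, on the genes drawn from, or on both. C2H2 zinc finger genes, at 21.3% against 14.6%, did not pass (n = 178 genes, adjusted p = 0.0560).

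The stacking of CPT half-lives at 24 h has several possible sources. Of 284 genes with a control half-life under 1 h, 75.4% stood at the limit after CPT (95% interval 69.9 to 80.3), which argues against stable genes as the whole cause. The share at the limit was 94.6% in the highest quintile of the 4sU signal and 85.4% in the lowest, so it was not higher at low signal. The 4sU signal gives no RNA level of the CPT arm, so low abundance after CPT stays open. Of the 585 fastest control genes, 22.4% were below the limit after CPT (95% interval 19.1 to 26.0), against 7.27% by chance. A single offset in scaling without error per gene would keep the order of genes and so place all 585 below it. Over 50% was only the bound set for calling such an offset. An offset with error per gene stays open because no error is given. A slower decay after long CPT treatment, the biological difference in the design, stays open as well, and these cannot be told apart here.

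Mesenchymal markers in the 4sU signal may come from RNA of another cell type. A second list of 25 fibroblast genes was written after the first markers were seen and without any gene looked at before. Of these, 80% had a signal above the median of genes with a half-life and 3 were listed at 0. Among the 20 above the median were LOXL2 (412), COL5A1 (129) and DCN (43.5), and 14 of these 20 had no control half-life. Part of the list was also measured in the time courses. A control half-life was listed for 6 of the 25 genes, COL5A1 at 7.13 h among them. A CPT half-life was listed for 9, LOXL2 at 24 h among them. Of 193 other nuclear genes with a signal of at least 162, 19.7% had no control half-life (95% interval 14.3 to 26.0), an interval below the over 50% expected if a filter took out such genes in general but reaching past the bound of 25%, so only a partial filter stays open for VIM, COL1A1, COL1A2 and SPARC. In the second list, 7.14% of the 14 genes above the median without a control half-life reached that signal (LOXL2, at 412, 95% interval 0.181 to 33.9). A filter that starts at a signal of 162 could not have taken out the rest of these 14. That signal was set from the first markers, and it decides nothing about a filter that starts lower. COL3A1 (44.71), CDH2 (25.57), ACTA2 (12.51) and ZEB1 (8.575), first markers without a control half-life, lie below it too. A filter that starts at a lower signal was not tested. Whether 1 or both libraries carried this RNA, and whether it came from other human cells, from reads of another species or from a change in the MCF7 cells themselves, was not tested.

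Gene length did not account for the relation of 4sU signal and control half-life, since the partial rho given transcript length and gene span was 0.150, against 0.121 without them (9410 genes, p = 1e-05, the smallest the permutations can give). No biological explanation was tested for it. Longer transcripts had shorter control half-lives (rho = -0.246, p = 1e-05).

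AU-rich pentamers were tested as a hypothesis for short half-lives, over 8893 protein-coding genes with a 3-prime UTR of at least 50 nt. Pentamers per kb had a rho of -0.0283 with the control half-life (p = 0.00762, permutation test), with r = -0.0128 (p = 0.231). Given the length of the 3-prime UTR the rho was 0.0142 (p = 0.179), so the density of pentamers decided nothing. Genes without a pentamer had a median of 9.52 h, and the densest decile of genes with one had 7.77 h. The median over all protein-coding genes was 7.32 h, below both, so the half-life did not fall steadily with density.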
